A study of Drosophila melanogaster with 6 samples.

How the data were processed

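RNA was measured in 6 libraries of GFP-labelled outer proliferation centre neuroepithelial cells, 3 dorsal and 3 ventral, grouped by the sample titles. Per the labels' protocols, larvae were raised at 25 °C, cells were drawn by glass micropipette within 1 h, cells of 3 to 4 brains were pooled per sample, and libraries were made with a SMART-Seq v4 kit and a Nextera XT kit. The deposited counts are whole numbers of reads per gene that the authors did not normalize. Per the submitters' processing notes, Trimmomatic, featureCounts and DESeq2 were used with the builds dm6 and BDGP6, and the aligner, tool versions and strandedness are not given in the sources used here. The deposited normalized counts, a signal scale made by the authors, equalled the counts divided by 1 factor per library, with 0 values off by more than 0.01.

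Identifiers were matched to the BDGP6 annotation: 17253 of 17559 (98.3%) had a symbol. The 306 others were kept and tested under their identifiers. List genes with no match by symbol (disco-r, wg, L, scro, para, VAChT, btl, Med, ds, Mcm3, br, Imp, 18w, Fas1, hbs and ap) were not analysed here by name, and any of them could be among the identifiers without a symbol.

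Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit, group as the only term), with Benjamini-Hochberg adjustment over 8707 genes and a threshold of 0.05. SE is the absolute log2 fold change over the square root of the F statistic. The labels do not say whether samples were taken on separate days, so p-values measure the spread between these pooled samples. Total counts were 21114019 to 27815885 per library. A count of 0 was taken to allow up to 3 reads, and such floors and all read intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise.

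There were 29 lists fixed before the data were examined: the genes of the title, domains of the other axis, eye disc dorsal-ventral patterning, neuroepithelium, neuroblast, medulla temporal factors, neuron, glia, lamina, inner proliferation centre, Hox, non-neural cells, eye disc, male dosage compensation, Notch, EGFR, Hedgehog, Wnt, BMP, JAK/STAT, Hippo, cell cycle, ecdysone and timing, adhesion and guidance, Dpr and DIP, patterning transcription factors, stress, ribosomal protein and mitochondrial genome. The 22 lists with at least 5 tested genes, the title genes aside, were tested with limma 3.58.1 (camera with a preset correlation of 0.01 on log2 CPM with a prior count of 2, camera with an estimated correlation, and fry). Named genes were the Spalt and disco genes, up to 10 genes per direction past the threshold whose groups do not overlap, up to 4 called members of each list or otherwise 2 with the smallest p as values, the 5 smallest p in a direction with fewer than 5 calls, and the 3 largest called folds per direction with a mean of at least 10 CPM. Any other gene named was chosen after its values were seen.

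Counts were simulated for the same genes and libraries, with 50 genes changed at each fold and every gene drawn independently. The dorsal against ventral test (8707 genes) recovered 75.5% of tested genes changed 4-fold, 79.6% at 8-fold, 93.9% at 32-fold and 96.0% at 128-fold. Of 183 calls, 13 (7.10%) were false. With 183 calls the adjustment is less strict than with the 8 calls of the real data. These shares therefore do not give the power of the real test. Alternatives were RLE and upper-quartile factors, library size alone, DESeq2 1.42.0, limma-voom with sample weights, limma-trend on the deposited normalized counts, other filters on low counts and other thresholds, the replicate number as a block, and each library left out in turn. Leaving out ventral replicates 1 and 2 together and a roX2 covariate were added after seeing the data. Intervals were computed with scipy 1.17.1.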

Results

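The outer proliferation centre is the neuroepithelium of the larval optic lobe of Drosophila melanogaster that gives rise to the medulla. Polyadenylated RNA was measured in GFP-labelled neuroepithelial cells drawn by micropipette from the dorsal or the ventral part of this tissue in late second-instar brains that the labels give as female. There were 3 dorsal and 3 ventral libraries, each from cells of 3 to 4 pooled brains. Counted reads numbered 25340188, 27815885 and 26032653 in dorsal replicates 1, 2 and 3. They numbered 26259242, 21114019 and 24355227 in ventral replicates 1, 2 and 3. The comparison of dorsal with ventral asks which genes separate these parts of the neuroepithelium. The title of the series names the Spalt and Disco transcription factors. Levels are in CPM (read counts scaled to a common library total), given as mean ± SD over 3 libraries, and log2 fold changes are dorsal minus ventral ± SE.

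The Spalt genes marked the dorsal cells and disco marked the ventral cells. Spalt-related (salr, FBgn0000287, chromosome 2L, 11358873 to 11373636, plus strand) stood at 47.6 ± 12.3 CPM in dorsal and 0.202 ± 0.077 CPM in ventral libraries. Its log2 fold change was 7.87 ± 0.42, a fold of 234 (adjusted p = 3.25e-05, edgeR). Spalt major (salm, FBgn0261648, chromosome 2L, 11434311 to 11445614, minus strand), which like salr encodes a zinc finger transcription factor, stood at 44.3 ± 13.6 CPM in dorsal and 0.252 ± 0.187 CPM in ventral libraries. Its log2 fold change was 7.37 ± 0.53 (166-fold, adjusted p = 0.000185, edgeR). The zinc finger gene disconnected (disco, FBgn0000459, chromosome X, 16210598 to 16216750, minus strand) went the other way, with 1.77 ± 1.60 CPM in dorsal and 43.5 ± 15.7 CPM in ventral libraries. The log2 fold change was -4.61 ± 0.60 (24.5-fold, adjusted p = 0.0202, edgeR). The ventral level of salr was 0.425% of its dorsal level and that of salm 0.568%, while the dorsal level of disco was 4.08% of its ventral level. Reads of disco numbered 16, 31 and 94 in dorsal replicates 1, 2 and 3 and 1620, 741 and 791 in ventral replicates 1, 2 and 3. Each of the 3 genes separated all 3 dorsal from all 3 ventral libraries. The call of disco passed in 10 of 17 alternatives. Its 7 losses included those with no filter on low counts (adjusted p = 0.200, edgeR) and with the replicate number as a block (0.165, edgeR). The call was also lost without dorsal replicate 1 (adjusted p = 0.0735, edgeR), dorsal replicate 2 (0.127), ventral replicate 1 (0.0532) or ventral replicate 3 (0.0562). The last loss was with ventral replicates 1 and 2 left out together, which leaves 1 ventral library. The log2 fold changes in these 7 fits lay between -4.84 and -4.20. Without dorsal replicate 3, which held the most dorsal disco reads, the log2 fold change was -5.65 and the call held.

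**Figure D1:**
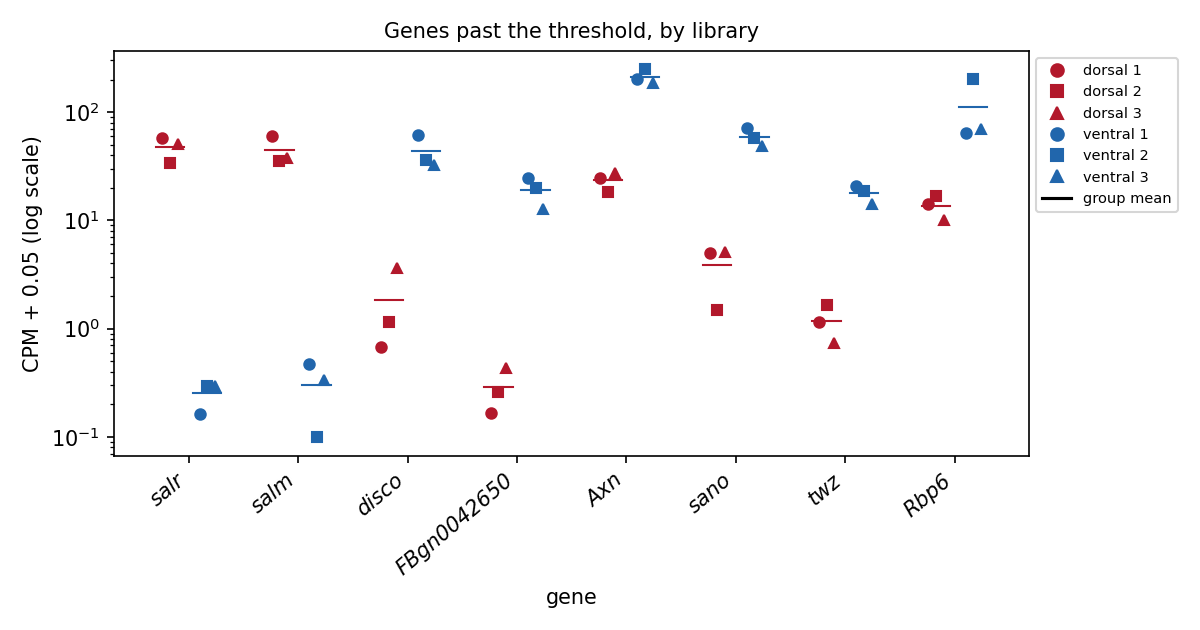
CPM plus 0.05 on a log axis for the 8 genes past the threshold, with 1 point per library (dorsal red, ventral blue, marker shape for the replicate) and a bar at each group mean. The dorsal and ventral libraries do not overlap for any of the 8 genes, and disco is highest among the dorsal libraries in replicate 3.

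Of 8707 genes tested, 2 were higher in dorsal (salr and salm) and 6 were higher in ventral cells at an adjusted p under 0.05 (edgeR quasi-likelihood test). Axin (Axn, FBgn0026597, chromosome 3R, 30022842 to 30035311), a scaffold of the complex that degrades the Wnt effector Armadillo, stood at 23.5 ± 4.57 CPM in dorsal and 211 ± 32.5 CPM in ventral libraries. Its log2 fold change was -3.17 ± 0.22 (9.00-fold, adjusted p = 0.000185). The gene FBgn0042650, whose identifier had no symbol in the annotation used, rose from 0.237 ± 0.134 CPM in dorsal to 19.0 ± 5.84 CPM in ventral libraries (log2 fold change -6.30 ± 0.57, adjusted p = 0.00129). The genes sano (chromosome 2R, 18878391 to 18959500) and twz (chromosome 2R, 21560246 to 21576035) had log2 fold changes of -3.95 ± 0.44 (adjusted p = 0.00739) and -3.97 ± 0.46 (adjusted p = 0.00861). The RNA-binding protein gene Rbp6 (chromosome 3L, 17058774 to 17238212) stood at 13.6 ± 3.45 CPM in dorsal and 111 ± 77.0 CPM in ventral libraries, a log2 fold change of -3.03 ± 0.44 (adjusted p = 0.0493). Exons of Axn share 302 bp with asRNA:CR44045 and 72 bp with ZIPIC on the opposite strand, and the strandedness of the counting is not given in the sources used here. The number of ventral genes fell to 2 without dorsal replicate 1, where sano (log2 fold change -4.19 ± 0.54, adjusted p = 0.0541), twz (-3.96 ± 0.56, 0.0872), disco (-4.22 ± 0.57) and Rbp6 (-3.06 ± 0.56, 0.472) missed the threshold in a smaller fit. When ventral replicates 1 and 2 were left out together, an alternative chosen after seeing the data that leaves 1 ventral library, Axn alone was called toward ventral. The log2 fold changes of the others in that fit were -5.72 ± 0.78 for FBgn0042650, -3.66 ± 0.56 for sano, -3.63 ± 0.65 for twz, -4.20 ± 0.75 for disco and -2.37 ± 0.32 for Rbp6. Rbp6 passed in 8 of 17 alternatives. It missed the threshold without dorsal replicate 2 (adjusted p = 0.176), dorsal replicate 3 (0.391) or ventral replicate 3 (0.0562), with RLE factors (0.0564), with a minimum of 10 reads in 3 libraries (0.0506) and with no filter (0.295), all by edgeR. Without ventral replicate 2 its log2 fold change was -2.30 ± 0.26.

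Beyond salr and salm, the dorsal genes with the smallest p did not pass the threshold with edgeR, but passed with DESeq2. The calcium channel gene cac had a log2 fold change of 1.65 ± 0.27 (adjusted p = 0.0960, edgeR), with 55.8 ± 18.2 CPM in dorsal and 17.8 ± 1.79 CPM in ventral libraries. The sodium channel gene rpk had 9.62 ± 1.75 CPM in dorsal and 1.84 ± 0.61 CPM in ventral libraries, and the ligand gene Wnt2 had 85.9 ± 26.1 and 39.8 ± 1.2 CPM (adjusted p = 0.494 for each, edgeR). DESeq2 gave adjusted p-values of 1.38e-05 for cac, 2.23e-06 for rpk and 0.0115 for Wnt2, and edgeR with no filter on low counts also called cac (0.000315) and Wnt2 (0.0297). The exons of rpk share 1531 bp with asRNA:CR44155 on the opposite strand, so reads of this pair cannot be told apart without strand.

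Among signalling lists fixed before the data were examined, the Wnt list held the single gene past the threshold over all genes. Of 14 tested Wnt genes, Axn was called toward ventral, and adjusted over the list alone 3 passed, with Wnt2 toward dorsal and Wnt4 toward ventral. Wnt4 had a log2 fold change of -2.99 ± 0.61 (adjusted p = 0.418 over all genes, edgeR, and 4.68e-05, DESeq2). Its reads numbered 2092 in ventral replicate 1 against 436 and 393 in ventral replicates 2 and 3. The list had a median log2 fold change of 0.20 and a mean of -0.23. Camera did not call it (ventral direction, adjusted p = 0.835, limma). That direction was dorsal when dorsal replicate 3, ventral replicate 1 or ventral replicate 2 was left out. Fry's mixed test of change in either direction gave an adjusted p of 6.53e-05. The list includes Axn, which passed on its own. No test without Axn was run, so this value does not show a change across the pathway. The mixed call was lost with the replicate number as a block (adjusted p = 0.323, fry). It was also lost with ventral replicates 1 and 2 left out, which leaves 1 ventral library. With edgeR none of 18 Notch, 11 EGFR, 9 Hedgehog, 10 BMP, 5 JAK/STAT and 14 Hippo genes tested passed over all genes or adjusted over the list alone. Examples are the Notch ligand gene Ser at 4.31 ± 0.27 CPM in dorsal and 1.33 ± 0.96 CPM in ventral libraries, neur at 192 ± 27.8 and 250 ± 43.4 CPM, gbb at 95.5 ± 14.5 and 67.0 ± 8.09 CPM, and spi at 655 ± 62.3 and 547 ± 78.2 CPM. Exons of neur share 1673 bp with asRNA:CR31429 on the opposite strand.

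Genes that divide the neuroepithelium along its other axis did not separate the groups. With edgeR none of 8 tested genes of this list passed over all genes or adjusted over the list alone, and brk stood at 119 ± 36.1 CPM in dorsal and 142 ± 26.6 CPM in ventral libraries. The gene bi had 89.0 ± 19.5 CPM in dorsal libraries and 7237 reads in ventral replicate 1 against 1262 and 1330 in ventral replicates 2 and 3. None of 15 neuroepithelial genes, 13 medulla temporal genes, 24 cell cycle genes, 13 ecdysone and timing genes, 14 stress genes or 3 tested genes of eye disc dorsal-ventral patterning passed by either adjustment. In these lists crb stood at 30.6 ± 10.05 and 21.9 ± 5.80 CPM, E2f1 at 270 ± 30.0 and 216 ± 18.1 CPM, mamo at 1728 ± 232 and 1418 ± 70.6 CPM, and tll at 153 ± 112 and 223 ± 71.2 CPM in dorsal and ventral libraries. Exons of E2f1 share 283 bp with asRNA:CR46055 on the opposite strand. In the eye disc dorsal-ventral list the tested genes were fng, Ser and Delta. The genes mirr, ara, caup and pnr were too low to be tested, so nothing is concluded about them. Reads of ara in replicates 1, 2 and 3 numbered 0, 25 and 33 in dorsal and 1, 2 and 3 in ventral libraries. Those of caup numbered 1, 14 and 8 and 0, 4 and 1. Those of mirr numbered 3, 1 and 13 and 2, 2 and 2, and those of pnr 1, 7 and 0 and 1, 1 and 1.

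Camera with its preset correlation (limma) called 2 of 22 lists, both toward ventral. Of 14 tested genes for Dpr and DIP immunoglobulin proteins, which pair on the surfaces of neurons, 12 had higher values in ventral libraries (median log2 fold change -0.92, adjusted p = 0.000463, but adjusted p = 0.991 with an estimated correlation). DIP-eta stood at 2.42 ± 0.54 and 8.07 ± 3.34 CPM and dpr7 stood at 32.6 ± 14.4 and 75.2 ± 25.4 CPM in dorsal and ventral libraries. Of 31 tested patterning transcription factor genes, 21 had higher values in ventral libraries (median -0.11, adjusted p = 0.0342, but adjusted p = 0.991 with an estimated correlation). Among them kn stood at 7.63 ± 2.76 and 19.4 ± 6.16 CPM and zfh2 at 9.40 ± 5.24 and 30.8 ± 22.5 CPM. With edgeR no member of either list passed over all genes or adjusted over the list alone. DESeq2 called DIP-eta over all genes (log2 fold change -1.75 ± 0.44, adjusted p = 0.0224). Without ventral replicate 1 no list was called by camera, and without ventral replicate 2 the Dpr and DIP list missed the threshold (adjusted p = 0.0703). With both left out, the libraries in which neuron genes such as nSyb were high, its direction was dorsal (adjusted p = 0.878). The patterning list was also lost without dorsal replicate 1 (0.157), dorsal replicate 3 (0.446) or ventral replicate 2 (0.172). Of 33 adhesion and guidance genes, 22 had higher values in dorsal libraries (kirre at 15.2 ± 5.64 and 6.50 ± 2.39 CPM), and of 81 ribosomal protein genes 65 had higher values in ventral libraries, without a call for either list over all 6 libraries. Camera called the ribosomal protein list without dorsal replicate 1 (adjusted p = 0.00131) and without ventral replicate 2 (0.00256), and the adhesion list without dorsal replicate 3 (0.0346) and without ventral replicate 2 (0.000141). With an estimated correlation these calls were lost (adjusted p = 0.981 without dorsal replicate 1, 0.932 without ventral replicate 2 and 0.903 without dorsal replicate 3). With ventral replicates 1 and 2 both left out, camera called the ribosomal protein list (0.0123) toward ventral and the adhesion (0.0352) and Notch (0.0123) lists toward dorsal, with an adjusted p of 0.934 for each with an estimated correlation. It called the Hedgehog list toward dorsal without dorsal replicate 2 (0.0441), and the neuron list toward ventral without ventral replicate 3 (0.000374). Both were lost with an estimated correlation (adjusted p = 0.843 and 0.251).

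Markers of other cell types varied between libraries within both groups. Of 9 neuron genes tested with edgeR none passed over all genes, although cac passed with DESeq2 (adjusted p = 1.38e-05) and with no filter on low counts (0.000315). Adjusted over the list alone 4 passed, cac toward dorsal and nSyb, Syt1 and brp toward ventral. The synaptic vesicle gene nSyb stood at 39.0 and 6.63 CPM in ventral replicates 1 and 2, at 0.618 CPM in ventral replicate 3 and at 1.25 ± 0.34 CPM in dorsal libraries. The active zone gene brp stood at 6.71, 20.8 and 6.22 CPM in the ventral and 3.35 ± 1.08 CPM in the dorsal libraries. The pan-neuronal gene elav was abundant in all 6 libraries, from 235 CPM in dorsal replicate 3 to 583 CPM in ventral replicate 2. None of 9 glia genes, 10 neuroblast genes, 7 lamina genes, 4 genes of non-neural cells or 3 eye disc genes passed by either adjustment. Neuroblast genes were nevertheless read in both groups. For example, ase stood at 325 ± 137 and 370 ± 73.0 CPM and dpn at 32.2 ± 9.73 and 51.2 ± 25.8 CPM in dorsal and ventral libraries. Of 5 inner proliferation centre genes kn alone passed adjusted over the list alone. The glial gene wrapper had 25, 217 and 68 reads in dorsal replicates 1, 2 and 3 and 607, 10 and 66 in ventral replicates 1, 2 and 3, and Gs2 had 8, 266 and 164 in the dorsal and 298, 8 and 11 in the ventral libraries. None of the 8 Hox genes was tested, as their reads were between 0 and 26 per library. The 37 genes of the mitochondrial genome held 0 reads in every library. This cannot be told from a genome left out of alignment or counting, so it is no result about expression.

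The dosage compensation RNAs roX1 and roX2, which are made mainly in males, were read in libraries labelled female. lncRNA:roX2 had 16000, 7580 and 0 reads in dorsal replicates 1, 2 and 3 and 6888, 62 and 5680 in ventral replicates 1, 2 and 3. The count of 0 allows up to 0.115 CPM. lncRNA:roX1 had 84065, 40834 and 12650 reads in the dorsal and 39513, 9246 and 34262 in the ventral libraries. The gene msl-2 had 2067, 1042 and 641 in the dorsal and 1042, 575 and 1341 in the ventral libraries. None of these 3 genes passed the test between dorsal and ventral over all genes or adjusted over the list alone. With the log2 CPM of lncRNA:roX2 as a covariate, an alternative chosen after seeing the data, 2 genes were higher in dorsal and 5 in ventral, and Rbp6 was lost (adjusted p = 0.109, edgeR).

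**Figure D2:**
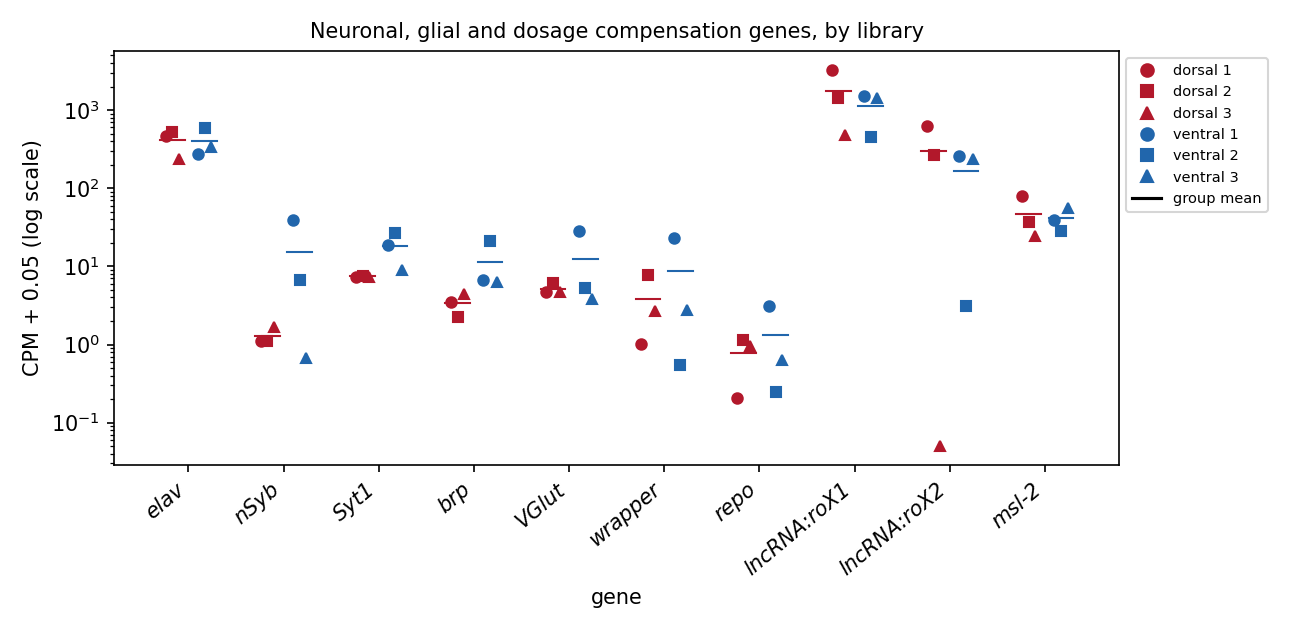
CPM plus 0.05 on a log axis for neuronal, glial and dosage compensation genes, with 1 point per library (dorsal red, ventral blue, marker shape for the replicate) and a bar at each group mean. nSyb and wrapper are highest in ventral replicate 1, and lncRNA:roX2 is lowest in dorsal replicate 3 and ventral replicate 2.

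The whole transcriptome did not divide by group. The leading principal component of log2 CPM held 32.4% of the variance and set ventral replicate 1 apart, and the next held 24.6% and set ventral replicate 2 apart. Across genes, which are not independent replicates, ventral replicate 3 had Pearson correlations of 0.956, 0.963 and 0.961 with dorsal replicates 1, 2 and 3, and of 0.936 and 0.944 with ventral replicates 1 and 2.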

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

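The alternative without ventral replicates 1 and 2 and the one with lncRNA:roX2 as a covariate were chosen after the results were seen. salr and salm kept their direction and their call in every alternative run, with leave-one-out log2 fold changes of 7.56 to 8.06 and 6.94 to 7.92. All 8 called genes were shared with the upper-quartile, library-size, DESeq2, limma-voom (9 ventral genes) and limma-trend fits. DESeq2 called 14 genes toward dorsal and 35 toward ventral and put 2.23% of list members past the threshold, against 1.11% in the main fit. The list members called in the main fit were the title genes salm, salr and disco, and Axn. The cause of the difference was not tested. With no filter on low counts 4 genes were higher in dorsal and 9 in ventral, sharing 6 of the 8 calls, and disco had a log2 fold change of -4.62 and missed the threshold (adjusted p = 0.200); the cause was not tested. Leaving out each library in turn gave 2 to 3 dorsal genes, 2 to 6 ventral genes, 0.836% to 1.11% of list members, a disco log2 fold change of -5.65 to -4.22 and 0 to 3 called lists, not the same lists in each fit, in fits with fewer samples. With ventral replicates 1 and 2 left out together, where the lone ventral library is assumed to vary like the dorsal ones, 1 ventral gene was called and disco had -4.20 (adjusted p = 0.396). Over all alternatives the adjusted p of disco ran from 2.11e-15 to 0.396. Estimated correlations and fry in one direction each called 0 lists; fry does not compare a list with other genes.

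Same-numbered libraries did not deviate together (correlations of 0.003, -0.04 and 0.06), which shows no strong shared effect of the number. It cannot tell whether same-numbered samples came from the same brains or the same day. With the replicate block 2 dorsal and 5 ventral genes were called, and disco had -4.84 (adjusted p = 0.165), a call lost in a fit with fewer residual degrees of freedom. The mixed fry test of the Wnt list was also lost there (adjusted p = 0.323).

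Signs turned only in genes that were not called, and the cause was not tested. With ventral replicates 1 and 2 left out, log2 fold changes were 1.01 for nSyb, 0.042 for Hsp68, 0.23 for Eip75B, 0.32 for dpn, 0.70 for bi and -0.22 for msl-2. Limma-voom gave 0.33 for bi, -0.067 for lncRNA:roX1 and -0.337 for msl-2. Leave-one-out values ran from -3.77 to 0.28 for Hsp68, -0.93 to 0.61 for bi, -0.22 to 1.07 for lncRNA:roX1, -4.60 to 0.67 for sad and -0.42 to 0.51 for msl-2.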

Other observations

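The tests in this part were chosen after the results were seen, apart from the splits of the libraries, and the genes named here outside the rule were chosen after their values were seen. The Wnt ligand gene Wnt10 had 82 reads in dorsal libraries (12, 64 and 6) and 1 in ventral libraries, a ratio of 74.3 with an exact 95% counting interval of 12.96 to 2969. Wnt10 was too low to be tested in the main edgeR fit. With no filter on low counts edgeR gave an adjusted p of 0.583, and DESeq2 gave 0.0942. DESeq2 also called Inos toward ventral (log2 fold change -2.02 ± 0.33, adjusted p = 6.47e-07), where edgeR gave 0.0960 and, with no filter on low counts, 0.000339. It called Obp99a toward ventral (-1.01 ± 0.21, adjusted p = 0.000916; edgeR 0.209, and 0.00925 with no filter) and Spn77Ba toward dorsal (2.34 ± 0.48, adjusted p = 0.000681; edgeR 0.844, and 0.158 with no filter).

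Other splits of the 6 libraries into 3 and 3 were run for the 8 genes past the threshold. The real split gave 8 genes and the highest of the other splits 0, and 1 of 10 splits gave as many as the real one; 10 splits are too few for a share under 0.05.

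lncRNA:CR46111 (chromosome 3R, 30026218 to 30026872) lies inside an Axn intron (30025540 to 30027360) on the same strand and had 200 reads in ventral and 1 in dorsal libraries. It did not pass in the main edgeR fit (adjusted p = 0.105), but passed with no filter on low counts (0.00925, edgeR) and with DESeq2 (1.12e-05). Unspliced Axn transcripts as the source would give the lncRNA an equal share of Axn reads in both groups. The share was 1.35% in ventral and 0.0535% in dorsal libraries, an odds ratio of 25.2 (exact 95% interval 4.46 to 1000.1, counting error only), which argues against a constant unspliced share. A ventral transcript of its own or a different rate of splicing stays open, and neither was tested.

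Several neuronal genes were high in ventral replicates 1 and 2, and differentiated neurons carried along with the picked cells are a candidate source that was not settled. Of 9 tested neuron genes, 5 stood above every dorsal library in ventral replicate 1 and 7 in ventral replicate 2. The gene cac went the other way, at 17.2 and 19.8 CPM in these libraries against 74.8, 38.6 and 54.0 CPM in dorsal replicates 1, 2 and 3. The median of the neuron list stood at the 99.99 and 99.94 percentile of 10000 random lists matched on expression, with log2 ratios to the dorsal mean of 0.98 and 0.88, but this restates the pattern and does not support any source. Dorsal replicate 2 also stood at a high percentile (99.42), with a ratio of 0.25, and ventral replicate 3 at a low one (0.58), with -0.44. Extreme values in both groups and directions mean that random lists may be too narrow a comparison. The most abundant neuron gene, elav, was not raised in ventral replicate 1 (274 CPM). It stood at 583 CPM in ventral replicate 2, against 470, 521 and 235 CPM in dorsal replicates 1, 2 and 3. The high level of elav in all libraries would hide a small share. Greater depth is argued against for ventral replicate 2, whose total was 0.822 of the median of the other 4. Ventral replicate 1 had 26259242 reads. Dorsal replicate 2 was deeper (27815885) with a list ratio of only 0.25, and dorsal replicate 3 was close in total (26032653) with -0.047. Levels in CPM are also scaled to the library total. These values argue against greater depth as the source for ventral replicate 1 too. For the 6 ventral genes, the smallest log2 ratio of ventral replicate 3 to the dorsal mean was 2.36. Their log2 fold changes without ventral replicates 1 and 2 lay between -5.72 and -2.37. These genes were called in a fit that included ventral replicate 3, so high values there were partly fixed by the selection. With 1 ventral library left, a contribution of neurons stays open, and no biological explanation was tested.

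disco stood in dorsal replicate 3 at 8.27% of its ventral mean (exact 95% interval 6.68 to 10.1). Ventral cells carried into that sample would bring FBgn0042650 at a like share, and it stood at 2.01% (0.964 to 3.70). This gene was chosen as the called ventral gene with the fewest dorsal reads, so its low share was partly fixed by the choice. The comparison therefore argues only weakly against carried cells as the whole source. The shares of the other ventral genes were 3.87% (2.29 to 6.12) for twz, 8.58% for sano, 8.97% for Rbp6 and 12.9% for Axn, and their log2 ratios to the mean of all 3 dorsal libraries were -0.64, 0.40, -0.45 and 0.22, against 0.52 for FBgn0042650 and 0.98 for disco, so a smaller carried share is not excluded. The intervals cover counting error only and treat the ventral means as fixed. Low dorsal expression of disco stays open and was not tested.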
